A study of Mus musculus with 2 samples.

How the data were processed

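Total RNA of G2N2C mouse BCC cells was extracted with Trizol and purified on a column, labelled with Cy3 or Cy5 with a kit for miRNA arrays of locked nucleic acid probes, and hybridised to 2 arrays, per the labels. On the first array the D3-interfered pool carried Cy3 and the control pool Cy5; on the second the dyes were exchanged. Each pool held RNA of 3 experiments. Both arrays hold the same pair of pools, so they count as 1 replicate and their spread is technical.

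The value table that the authors deposited holds 1 processed log2 dye ratio per array for 2244 features. It is in one dye order on both arrays. The log base, the centring and the dye order are not given in the sources used here. The column medians were 0.039 and 0.040. A log2 scale was taken because the mean turned value followed the log2 fold change of the other table, with r = 0.83 over 1677 probes and a slope of 0.77 at average intensities from 9 to 12, where natural logs would give 1.44; above 12 the slope was 1.34 over 27 probes. The other table that the authors deposited holds, per the file headers, a log2 fold change, an average log2 intensity, an unadjusted p-value and a signed fold change for 2101 probes. Its columns carry the names used by limma's result tables; the tool, background correction and normalization are not given in the sources used here. A fold change is missing there for 424 probes, none brighter than 6.99 on the average log2 intensity, which ran from 6.37 to 14.8. A deposited unadjusted p-value under 0.05 is given for 227 probes, where chance alone would give 83.9; what served as its replicates is not stated, so these p-values were not used.

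The first array was given the opposite sign, and both arrays were averaged. The sign of the mean follows the authors' fold change; which pool a positive sign favours stays open, and the comparison planned as higher or lower after interference is therefore reported as the side of miR-21 or the opposite side. Used were 376 probes for mouse miRNAs with a fold change in the authors' table, for 373 miRNAs. Left out were 1586 probes for near homologues of other species, 77 additional and 14 unknown probes, 2 mismatch probes and 46 mouse probes without a fold change. These 46 are called dim probes in the alternatives, though some of the probes kept were as dim. Probes of 1 miRNA were averaged. This concerned 3 miRNAs, of which the probes of miR-298 (-0.32 and 0.64) and of miR-744 (-0.32 and 0.15) disagreed in sign. miRNA names are those of the array's design and can be old.

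A miRNA passed the rule of size when both turned arrays had the same sign and the mean reached 1.5-fold, or 0.585 on the log2 scale. The same count with the sign of the second array exchanged serves as a technical comparison. For a list with at least 3 measured members, its median was placed among those of 10000 random lists of the same size drawn from the same 5 intensity bins, as a description of these arrays. Named in the text are, by a rule set before the data were examined, the 10 highest and 10 lowest miRNAs with the same sign on both arrays, miR-21, both arms of miR-214, the highest and lowest member of each list, and members needed to describe a list's count. The 21 lists were also set before the data were examined. Lists share members, among them miR-21, miR-143 and the miR-200 family. The array's miR-208 and miR-128a/128b, whose names differ from those in the lists, were not matched. The thyroid-hormone-linked and muscle lists therefore lack miR-208 (-0.01), and the neuron list lacks miR-128a/128b (0.13).

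Alternatives were other size thresholds, median-centred arrays, each array alone, the authors' fold changes, brighter miRNAs only, all features, the dominant arm, and members with the same sign only. The dominant arm was the one with the higher average intensity, however small the margin, as for miR-145* (6.84) over miR-145 (6.83). Removal of a lowess trend on average intensity (span 0.3, over all probes of the authors' table), a mean without the demand on signs, and inclusion of dim probes were added after seeing the data. Arrays were simulated for 1677 probes with the fitted trend and normal noise of a single size, the same for every probe. Of changes of 1 on the log2 scale, the rule recovered 94.0% in 50 dim probes. In 50 probes at an average intensity of 9 or more it recovered 54.0%. With the trend removed these shares were 96.0% and 98.0%. Changes of 2 were recovered for 100.0% of 50 dim and 88.0% of 50 bright probes, and for 100.0% of both with the trend removed. Unchanged dim probes passed the rule in 1.4% of 1398 simulated cases. Single probes of the data can be noisier, as miR-433* with 0.54 and 3.94 on the arrays, trend removed. The trend put in was itself a fit by the same smoother. The simulated shares may therefore not carry over to the data. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 for lowess and matplotlib 3.10.9.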

Results

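MicroRNA levels were compared in cells of G2N2C, a mouse basal cell carcinoma (BCC) line, after interference with D3 and after transfection of a control oligonucleotide. D3 is the type 3 deiodinase, the product of Dio3, which inactivates thyroid hormone. Cells were grown in low calcium with 8% chelated serum and collected 48 h after transfection. RNA of 3 experiments per condition was pooled, and the pair of pools was hybridised on 2 two-colour miRNA arrays with the dyes exchanged. The arrays therefore hold 1 replicate per condition. The SDs given here are technical, taken over both arrays, no p-value between conditions was computed, and the number of arrays limits the precision. The Dio3 transcript itself was not analysed here, so the extent of the interference has no check in these data. After probes for other species and mouse probes without a fold change in the authors' table were left out, 373 mouse miRNAs were compared. No limit of brightness was set beyond that. Probes without a fold change reached 6.99 on the average log2 intensity. This is at percentile 35.9 of the 373, so many of these were as dim.

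The comparison asked which miRNAs differed between D3-interfered and control cells. The mouse miRNA that lay farthest from 0 was miR-21, a miRNA with a known oncogenic role in many tumours. Its mean log2 ratio was 3.60 ± 0.73 (technical SD, 2 arrays), a 12.1-fold difference between the pools, and it reached 3.08 on one array and 4.12 on the other. The authors' deposited table gives miR-21 a log2 fold change of 2.73, or 6.63-fold. Values are turned so that a positive sign points the way miR-21 does, which is also the sign of the authors' deposited table. The labels give the dye of each pool, but the sources used here do not state which dye is the numerator of the ratios. If the ratios are red over green, a positive value means a higher level in the D3-interfered pool; if they are green over red, it means a higher level in the control pool. Sizes and counts are therefore given without a direction, as on the side of miR-21 or on the opposite side.

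By a rule of size, the same sign on both arrays and a mean difference of at least 1.5-fold, 33 mouse miRNAs lay on the side of miR-21 and 12 on the opposite side. After miR-21 came miR-143, with 2.06 ± 0.43, and miR-138, with 1.45 ± 0.37. The next were miR-30a with 1.31 ± 1.10, miR-378 with 1.248 ± 0.37, miR-542-5p with 1.22 ± 0.86, miR-685 with 1.19 ± 0.25, miR-26a with 1.10 ± 0.71 and miR-99b with 1.09 ± 0.52. miR-433* had a mean of 2.27, but this rested on 1 array: it was 4.22 there and 0.33 on the other, and the authors' deposited table gives 0.11. On the opposite side, the farthest was miR-688 with -1.62 ± 0.62, followed by miR-370, a miRNA of the imprinted Dlk1-Dio3 region, with -1.47 ± 0.51. miR-677 had -1.31 ± 1.67, with -2.49 on one array and -0.13 on the other, and miR-455 had -1.13 ± 0.14. With the trend on average intensity removed, the arrays of miR-677 lay closer, at -1.625 and -1.368. The remaining members of the 10 lowest were miR-34c, miR-34b-5p, miR-34a, miR-141, miR-200c and miR-200b, described with their families below.

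**Figure D1:**
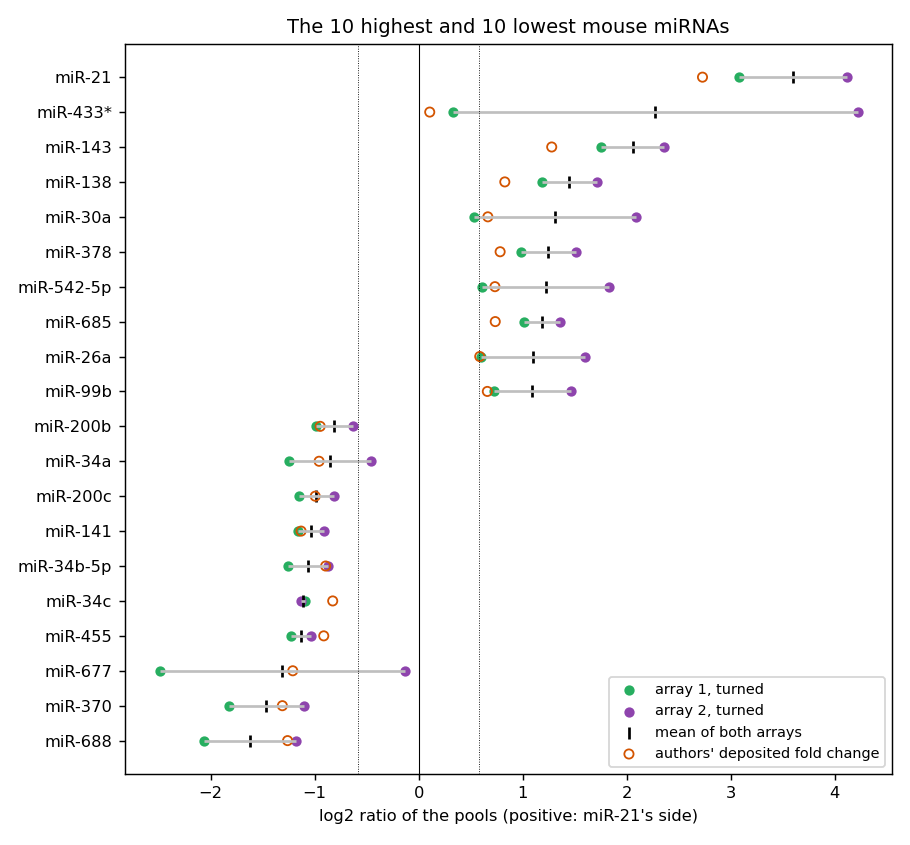
Log2 ratio between the pools (x axis) for the 10 highest and the 10 lowest mouse miRNAs with the same sign on both arrays; filled points are the arrays, ticks their mean, open circles the authors' deposited log2 fold change, and dotted lines the 1.5-fold size. miR-21 lies apart at a mean of 3.60, and the arrays of miR-433* lie far from each other, at 0.33 and 4.22.

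The deposited ratios kept a dependence on brightness: they correlated with average intensity across probes with r = 0.51 on the first array and 0.57 on the second. Across the 373 miRNAs, which are not independent replicates, the turned arrays correlated with Pearson r = -0.08 and Spearman rho = -0.05, and 39 miRNAs passed the same rule with the sign of the second array exchanged, against 45 with the signs as turned. When a smooth trend on average intensity was removed from each array, a step chosen after seeing the data, r was 0.43 and rho 0.22, and 50 miRNAs passed against 12 with the exchanged sign. Of the 45, 39 also passed with the trend removed, 27 on the side of miR-21 and all 12 on the opposite side. The balance of the sides differed between the sets of values: 73.3% of the miRNAs past the rule lay on the side of miR-21 as deposited, 60% with the trend removed (30 against 20), and 40% of those at 1.5-fold in the authors' deposited table (14 against 21), where signs per array play no part. Without the demand on signs the deposited ratios gave 69.0% (40 against 18). All 45 had the sign of the authors' deposited fold change, and 24 of them reached 1.5-fold there, 12 on each side.

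**Figure D2:**
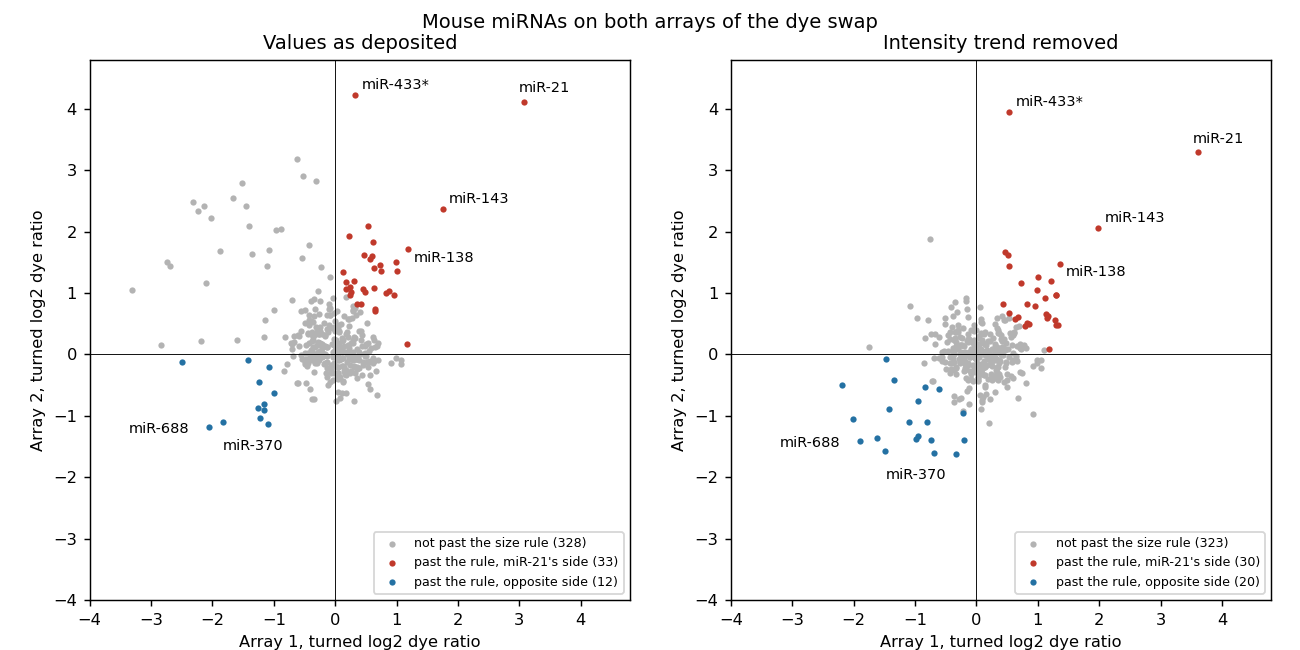
Turned log2 dye ratio of each mouse miRNA on array 1 (x axis) and array 2 (y axis), as deposited (left) and with the intensity trend removed (right); red and blue points pass the size rule on the side of miR-21 and on the opposite side. As deposited, 33 and 12 miRNAs pass and many bright ones lie in the upper left, where the arrays differ in sign; with the trend removed, 30 and 20 pass.

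The miR-200 family, which maintains the epithelial state by repressing Zeb factors, held 3 members on the opposite side: miR-141 with -1.03 ± 0.17, miR-200c with -0.98 ± 0.24 and miR-200b with -0.81 ± 0.25. With the trend removed their arrays lay further apart. The values were then -1.15 ± 0.64, -1.07 ± 0.45 and -0.98 ± 0.90, in the same order. miR-200b*, the other arm of the miR-200b hairpin, lay on the side of miR-21 with 0.63 ± 0.29, and the other 4 of the 8 measured members did not pass the rule. The median of the family was -0.18, at percentile 2.7 of random lists matched on intensity, and -0.42 in the authors' deposited table, at percentile 0.8. It was -0.48 and -0.16 on the single arrays, and -0.81 both over the dominant arms and over the members with the same sign on both arrays. The p53-linked list held the miR-34 miRNAs, direct targets of p53, all on the opposite side: miR-34c had -1.11 ± 0.03 as the mean of 2 probes, miR-34b-5p -1.06 ± 0.27 and miR-34a -0.85 ± 0.56. With the trend removed the technical SD was 0.26 for miR-34c, 0.01 for miR-34b-5p and 0.21 for miR-34a. In the same list miR-143 lay on the side of miR-21, and 9 of its 13 members did not pass. Its median was -0.02, at percentile 10.9, with -0.40 on the first array, outside the central 95% of random lists, and 0.17 on the second.

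In the miR-30 family, 5 of 7 measured members passed the rule on the side of miR-21 and none on the opposite side. miR-30d had 0.95 and miR-30e 0.75, with technical SDs of 0.12 and 0.38. As deposited, miR-30a, miR-30c and miR-30b were higher on the second array, with 0.54 and 2.09, 0.23 and 1.92, and 0.12 and 1.35 on the arrays. With the trend removed the arrays of these lay closer, with 1.295 and 0.974, 0.73 and 1.17, and 0.70 and 0.47. Those of miR-30d and miR-30e then lay further apart, with 1.165 and 0.624 (SD 0.38), and 1.096 and 0.072 (SD 0.72). The median of the family was 0.75, at percentile 99.1, with 0.48 and 1.03 on the single arrays, and it was 0.32 in the authors' deposited table, at percentile 98.0; with the trend removed 3 members passed, and the median was 0.58 at percentile 98.7. Its lowest member was miR-30a* with -0.08 ± 0.43, which is 0.15 in the authors' deposited table. Both miR-222, with 1.05 ± 0.82, and miR-221, with 0.97 ± 0.01, lay on the side of miR-21. With the trend removed miR-222 had 0.87 ± 0.40 and miR-221 0.90 ± 0.60, so the near identity of the arrays for miR-221 did not hold. The miR-23, miR-27 and miR-24 clusters had a median of 0.48, at percentile 89.0, and of 0.42 in the authors' deposited table, at percentile 98.6. As deposited 1 of 7 members passed the rule, miR-24-1*/24-2*. With the trend removed this was miR-27b instead, and the median was 0.22, at percentile 80.4. The median as deposited was -0.63 on the first array and 2.42 on the second. Bright members of the clusters differed in sign between the arrays, as miR-27b did with -0.63 and 3.18, and the lowest member was miR-27a* with 0.18. The miR-29 family had a median of 0.27, at percentile 95.1, with 0.12 and 0.22 on the single arrays and 0.09 at percentile 90.2 in the authors' deposited table, and no member past the rule, from miR-29c* with 0.11 to miR-29a with 0.51.

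Of 21 measured epidermal keratinocyte miRNAs, 4 passed on each side, from miR-21 to miR-141, and the median was 0.09, at percentile 29.9, and -0.05 with the trend removed; it was -0.56 on the first array and 0.39 on the second. Of 18 thyroid-hormone-linked miRNAs matched by name, 3 passed on the side of miR-21, namely miR-21, miR-378 and miR-31*, and none on the opposite side. The median was 0.22, at percentile 96.3, and the lowest was miR-761 with -0.27. The median was 0.09 on the first array and 0.33 on the second, and 0.09 in the authors' deposited table, at percentile 97.3. All 35 measured members of the Dlk1-Dio3 list have a gene between Dlk1 and Dio3 in the RefSeq gene table of GRCm38.p6, so they neighbour the gene that was targeted. Only miR-433* and miR-370 of these passed the rule, on different sides, and the median was -0.04, at percentile 2.8 and at percentile 21.9 in the values of the authors' deposited table. The list lay outside the central 95% of random lists with the trend removed (-0.06, percentile 2.4), over dominant arms and over members with the same sign on both arrays. Its median changed sign over brighter miRNAs, with 0.10, and was -0.13 on the first array and 0.005 on the second. miR-654-3p, a further measured miRNA with a gene there, is not in the list; it had -0.36 ± 0.46 and did not pass, and the median with it was -0.06. The Hedgehog-linked list, chosen because BCC is driven by Hedgehog signalling, had a median of 0.08, at percentile 42.2, which is -0.04 in the authors' deposited table, and 1 of 28 members past the rule, miR-324-5p with 0.91. Its highest member was miR-125b-5p with 1.19, which had -0.53 and 2.91 on the arrays, and its lowest miR-10a with -0.53. miR-214, which was named in advance, had 0.11 ± 0.76 and miR-214* 0.39 ± 0.37; both are negative in the authors' deposited table, with -0.15 and -0.04.

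The other miRNA families had medians near 0 over both arrays, which came from arrays of opposite sign in the let-7 family (-0.21 and 0.14), the miR-15 and miR-16 family (-0.36 and 0.30) and the miR-183 cluster (-0.32 and 0.42). The miR-17-92 and paralog clusters had a median of 0.08, at percentile 39.8, from miR-20b with -0.27 to miR-106a with 0.63, the single member of 18 past the rule, which it did not pass with the trend removed (0.55) or by its value in the authors' deposited table (0.26). The let-7 and miR-98 family had 0.08, at percentile 34.6, with none of 13 past the rule, from let-7f with -0.54 to let-7i with 0.59; its median is -0.12 in the authors' deposited table and -0.11 with the trend removed. The miR-15 and miR-16 family had -0.03, at percentile 17.5, with miR-15b past the rule at 0.62 and miR-503 lowest at -0.56; with the trend removed miR-15b, at 0.47, did not pass and miR-503, at -0.59, passed on the opposite side. The miR-183, miR-96 and miR-182 cluster had 0.06, at percentile 29.9, and -0.15 in the authors' deposited table, from miR-96 with -0.28 to miR-183 with 0.26. The hypoxia miRNA miR-210 had -0.28 ± 0.29.

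Markers of other cell types passed the rule in 1 case. Among 7 fibroblast and smooth muscle marker miRNAs this was miR-143; the list's median was 0.24, at percentile 95.6, 0.05 at percentile 83.7 in the authors' deposited table and 0.11 over the dominant arms, and the lowest member was miR-199a-5p with 0.01. No member passed among the blood cell markers, with a median of 0.06 at percentile 55.2, and -0.28 on the first array and 0.30, outside the central 95%, on the second, from miR-142-3p with -0.08 to miR-223 with 0.58, or among the muscle markers, with 0.11 at percentile 56.9, from miR-206 with -0.08 to miR-133b with 0.22. None passed among the neuron markers, with -0.06 at percentile 21.8, from miR-153 with -0.18 to miR-129-5p with 0.51, or the liver and gut markers, with -0.11 at percentile 6.6, from miR-215 with -0.24 to miR-122 with 0.20. The embryonic stem cell markers had 0.09, at percentile 79.6, from miR-291b-5p with -0.23 to miR-292-3p with 0.49, and no member past the rule. All embryonic stem cell and liver and gut markers were dim, below the median average intensity of 7.16, as miR-292-3p with 6.72 and miR-122 with 6.85. Values near 0 therefore do not show that their levels were alike. Dim members of the other lists included miR-153 with 6.67 and miR-142-3p with 6.95. In the authors' deposited table the medians of the muscle and embryonic stem cell lists are negative, with -0.04 and -0.06, as are the values of miR-223 and miR-292-3p, both -0.09.

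**Figure D3:**
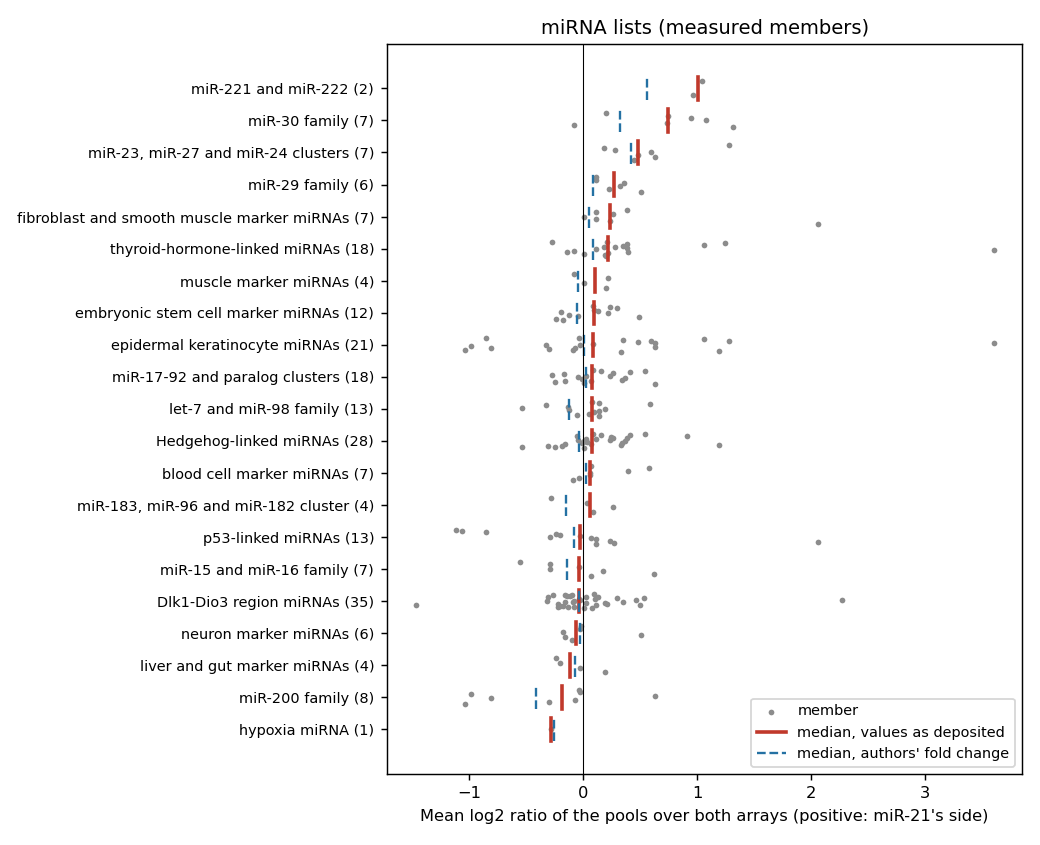
Mean log2 ratio between the pools over both arrays (x axis) of the measured members of each list (rows, number of members in brackets); grey points are miRNAs, red bars the list's median as deposited and dashed blue bars the median of the authors' deposited fold changes. As deposited, the medians of miR-221 and miR-222 (1.01) and of the miR-30 family (0.75) lie farthest on the side of miR-21; in the authors' deposited table the miR-23, miR-27 and miR-24 clusters (0.42) lie beyond the miR-30 family (0.32).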

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

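The tests in this part were chosen after the values were seen, except that the counts in the authors' deposited table were planned as an alternative. A signal outside the compared miRNAs was flagged at 1 feature of the value table, number 13138, which has no row in the authors' table and is unnamed here. It had -8.33 on the first array and -7.00 on the second before any sign was turned, while the next lowest mean of a feature was -1.53. The dyes were exchanged between the arrays, so values of the same sign before turning follow mainly the dye and not the pool.

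miR-21 stood apart from the other mouse miRNAs, with a mean of 3.60. Dye bias of its probe would give turned values of opposite sign; with the trend removed the dye part, the difference between the arrays divided between them, was 0.16 against a mean of 3.46, which argues against it. The same value of 3.46, close to that before the trend was removed, argues against the intensity trend as the whole source. A difference between the pools other than the interference cannot be told apart from it, since 1 pair of pools was measured. An effect of the interference stays open as a hypothesis, as does its direction.

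Members of the miR-200 and miR-34 families lay opposite miR-143 and miR-21. More fibroblast cells in one pool may contribute: the other 6 fibroblast markers had a median of 0.15 (SD 0.13 between markers) with the trend removed, far below 2.02 for miR-143, but only 1 of them was in the brighter part of the miRNAs, so this cannot be told apart. A lower share of keratinocytes would move their miRNAs alike. Of these miRNAs, 7 spanned 1.05 on the log2 scale, from miR-141 with -1.15 to miR-429 with -0.09, trend removed. The error of such a difference was 0.71, which leaves this open too. Both ends belong to the miR-200 family, whose side was to be explained. Only miR-203 and miR-205 of the 7 lie outside that family. The arrays of miR-205 differed in sign, with -1.076 and 0.786, trend removed. The 7 are part of the list of 21 keratinocyte miRNAs. Of the 21, 5 passed the rule on the side of miR-21, itself included, and 4 opposite with the trend removed. The labels name 1 cell line and no other cells. An effect of the interference was not tested apart from these.

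More miRNAs lay on the side of miR-21 than opposite, 73.3% of those past the rule. Normalization and the dye trend are a candidate explanation, and the values needed are there: the share was 69.0% without the demand on signs, 60% with the trend removed and 40% in the authors' deposited table (14 against 21 at 1.5-fold). The balance of the sides therefore gives no ground for a general shift.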

How the results depend on the processing

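Trend removal, the mean without a demand on signs and the inclusion of dim probes were added after seeing the data. The counts of 33 miRNAs on the side of miR-21 and 12 opposite stayed within 1.5 times under 2 robust SDs, median centring, the brighter miRNAs, the mean alone and dim probes. They became 59 and 23 at the lower threshold, 15 and 7 at 2-fold, 14 and 21 in the authors' deposited table, and 71 and 59 over all features, which holds more probes. With the trend removed the opposite side held 20. Each array alone gave 33 to 87 on the side of miR-21 and 17 to 52 opposite. The correlation of the arrays, -0.08, was -0.23 over all features, 0.059 over brighter miRNAs and 0.43 with the trend removed. The number of lists outside the central 95% of random lists, 1 as deposited (the miR-30 family), was 3 in the authors' deposited table, 2 over brighter miRNAs, 2 for dominant arms, 5 for members of the same sign and 3 with the trend removed, and 2 to 3 with 1 array alone. The miR-30 family was among them in all of these except dominant arms and the second array alone. The miR-200 family was among them in all of these except the values as deposited and the first array alone. By its definition the central 95% also leaves out some random lists. With this many lists, which share members, a count of 1 outside it is no evidence of a difference. The random lists were drawn without regard to family. A percentile near either bound has a sampling error of 0.16, and the miR-200 family as deposited, the thyroid-hormone-linked list in the authors' deposited table (percentile 97.3) the Dlk1-Dio3 list with the trend removed (2.4), the miR-30 family for dominant arms and for members of the same sign, and the p53-linked list for dominant arms lay within 2 such errors of it. Except for the larger probe set, the cause was not tested. Apart from the single arrays, 18 of 123 values of list medians and 15 of 199 of named miRNAs moved by more than the technical SD, and no named miRNA past the rule changed sign. miR-433*, with an SD of 2.755, was not counted although it went from 2.27 to 0.11 in the authors' deposited table. miR-221, with an SD of 0.01, was counted when it went from 0.97 to 0.90 with the trend removed. The technical SD is wide where the arrays disagree, so these counts are no measure of stability. For a miRNA, a single array cannot differ from the mean of both by more than that SD, so it gives no such check; on 1 of the arrays 15 of 53 named miRNAs and 12 of 21 list medians had the sign opposite to their mean. No value could be given for the embryonic stem cell and the liver and gut lists over brighter miRNAs, or for the blood cell list over members of the same sign, since no member was left. Loess from the intensities of each channel was not run, as these were not used here. Signal over background is not given for each array, and dim miRNAs limit what a value near 0 shows. No paired analysis was possible because the arrays hold 1 pair of pools.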

Other observations

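The sets described here were chosen after the values were seen. Removing the trend brought 11 further miRNAs past the rule, mostly bright ones whose arrays differed in sign as deposited. On the side of miR-21 these were miR-22 with 1.07, miR-27b with 1.07 and miR-125b-5p with 0.98. On the opposite side they included miR-801 with -1.53, miR-691 with -1.34, miR-689 with -1.16, miR-320 with -0.88 and miR-709 with -0.80. In the authors' deposited table miR-22 has 0.93, while miR-27b with 0.48 and miR-125b-5p with 0.43 do not reach 1.5-fold; miR-801 has -1.10, miR-691 and miR-689 -1.05, and miR-320 and miR-709 -1.11.

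The 44 measured miRNAs numbered from miR-676 to miR-721, which include miR-688 and miR-677, had a median of -0.08, of -0.11 with the trend removed, and of -0.06 in the authors' deposited table. Among random lists these lay at percentiles 0.1, 0.2 and 6.4. The 21 brighter members had medians of -0.14, -0.19 and -0.21 in the same order. Since the series was picked after its extreme members were seen, these percentiles are no evidence. miR-685 of the same series lay on the side of miR-21 with 1.19.

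Among 1230 near-homologue probes, which are not designed for the mouse, 66 passed the rule of size as deposited and 80 with the trend removed. With the sign of the second array exchanged 112 passed as deposited, a count that also holds the dye trend. The exchanged count with the trend removed is not given here, so the 112 does not set a noise level for the 80. Probe 14355 had -2.88 and -2.24, and probe 17400 had 2.40 and 2.36. The authors' deposited table gives -2.0 and 1.67 for them.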
